A study of Homo sapiens with 6 samples.

How the data were processed

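Gene expression was measured by RNA sequencing of total RNA from human fibroblasts and from fibroblasts undergoing microRNA-mediated conversion toward neurons, in 6 libraries that form 3 groups of 2. Control fibroblasts carried a control short hairpin RNA. MicroRNA cells expressed miR-9/9* and miR-124, small RNAs that are abundant in neurons, together with the same control hairpin. REST-hairpin cells expressed the same microRNAs together with a hairpin against REST, a transcription factor that represses neuronal genes in non-neuronal cells. Both microRNA groups were collected at day 7, per the labels; the labels of the control fibroblasts give no day. RNA was extracted with a PureLink column kit and made into standard Illumina libraries, per the labels' protocols.

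For each library, the authors deposited a table of 62893 Ensembl gene features with exon coordinates, a read count, a CPM value (count relative to the library total) and an RPKM value (the same per kilobase of exon), per the file headers. Reads were placed on the hg19 build, per the submitters' processing notes. The aligner, the counting program, the strand setting and the treatment of reads with several matches are not given in the sources used here. Checked against the files, the authors' CPM equals the deposited count divided by the total of its column, and their RPKM equals that CPM per kilobase of listed exons. The deposited counts are whole numbers that were not normalized, and every test used them; the deposited CPM and RPKM entered no test. Coordinates are those of the files, on hg19.

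Gene symbols came from a table of Ensembl identifiers and symbols, which matched 51537 of the 62893 features and 15771 of the 16191 features with at least 60 counts over the libraries. Of 719 list entries fixed before the data were examined, 711 matched a feature, 3 of them by an older symbol. X-inactivation and Y-linked features, 509 in all, were left out of every step. Library totals ran from 12754671 to 15782133 counts. Within each group the libraries differed by more than counting noise, with a chi-square per degree of freedom of 2.65 in control fibroblasts, 1.71 in microRNA cells and 2.04 in REST-hairpin cells, so each was kept as a replicate. Nothing in the labels says that the replicates came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

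Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as design, which left 17216. Libraries were scaled by TMM (trimmed mean of M-values), with factors of 0.822 and 0.820 in control fibroblasts, 1.12 and 1.12 in microRNA cells, and 1.09 and 1.09 in REST-hairpin cells. A quasi-likelihood model (glmQLFit, robust) with the group as the only term was fitted to all 6 libraries, so that the groups shared an estimate of spread. Each of 3 comparisons was tested with glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Expression levels are TMM-scaled CPM as mean ± SD of n = 2 libraries. Log2 fold changes come from the fit, with a standard error (SE) equal to the size of the fold change divided by the square root of its F statistic. For large folds on few counts this SE can be smaller than counting error, so it overstates the precision there. Where a group had 0 counts, a fold is a lower bound computed against a floor of 3 counts over the group's libraries, and where it had 1 to 3 counts the ratio is given with its 95% exact (Clopper-Pearson) counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

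Before the data were examined, 26 gene lists were fixed: REST corepressor and PRC2 components, canonical REST target genes, neuronal cytoskeleton and adhesion, presynaptic and vesicle release, voltage-gated channels, neurotransmitter receptors and postsynaptic proteins, neurogenic transcription factors, reported targets of miR-9/9* and miR-124, progenitor BAF and splicing factors, neuronal BAF and splicing factors, fibroblast matrix and identity, smooth muscle and contractile genes, skeletal muscle markers, cell cycle and DNA replication, p53 targets and growth arrest, interferon-stimulated genes, inflammatory and secretory cytokines, unfolded protein and amino acid stress, cholesterol synthesis, astrocyte and glial markers, neural progenitor markers, pluripotency markers, endothelial and blood cell markers, epithelial and melanocyte markers, mitochondrially encoded transcripts, and immediate early genes. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 25 lists with more than 1 measured member, with an estimated correlation and with fry beside it. A member rose or fell where its own adjusted p over all genes was under 0.05. Measured members are those that the filter kept, which may be expressed in 1 group only. Shares of measured members therefore do not cover members with few counts in every group.

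The genes named in the text follow a rule fixed at the same time. Per comparison they are 12 key genes (REST, RCOR1, EZH2, USP14, PTBP1, PTBP2, ACTL6A, ACTL6B, MAP2, TUBB3, SNAP25 and COL1A1), the 6 largest rises and 6 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, and up to 4 members of each list with the smallest adjusted p. Genes outside the rule are marked as chosen after their values were seen, and some genes that the rule takes are not reported here. The alternatives tried were DESeq2 size factors, library totals without TMM, the DESeq2 1.42.0 test, no filter on low counts, a fit of the compared groups alone, the replicate number as a term, a test against a fold of 1.5, and leaving out each library in turn. Removal of possible carry-over between libraries was added after the data were seen. No alternative for normalized values was needed, because the files held counts.

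The count test was tested on simulated data for the comparison of REST-hairpin with microRNA cells, drawn for 17216 genes from the means, spreads and library sizes of the data. It recovered 22% of genes changed 1.2-fold, 70% of those changed 1.5-fold, 76% of those changed 2-fold and 98% of those changed 4-fold, with 9 false calls among 142. That simulation changed 50 genes at each fold, far fewer than were called in the data. In a separate simulation a list of 30 genes raised 1.5-fold had a camera adjusted p of 1.45e-130, and 0 of 20 unchanged lists passed. Genes were drawn independently there, so the list test was not tried on genes that vary together. For the overlap of the comparisons that share the microRNA cells, 20 data sets with no effect were simulated. Short sequence motifs were counted in annotated 3' untranslated regions of GENCODE release 29, matched by gene identifier and without coordinates. The regression of fold change on each motif, with region length and base composition as terms, recovered a planted log2 effect of -0.3 as -0.34, with the lowest rank. Motifs were ranked by t, the effect divided by its SE, and not by the size of the effect. Pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used under Python 3.11.15.

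Strand use in counting is not given, so reads of a gene and of an overlapping antisense gene cannot be told apart. Of 194 named genes, 16 share over 10% of their exon bases with another feature, and their values are less certain. Among them, MYL9, HAND2, RBBP4, TUBA1A, TAGLN and ACTA2 share them with features on the opposite strand. TUBB3, GRIA1 and GOLGA7B share them with features on the same strand, which a strand setting would not separate. Those same-strand features held 0, 0 and 8 counts, and the treatment of reads that fall on such shared bases is not given.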

Results

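RNA was sequenced from 6 libraries of human fibroblasts in 3 groups of 2: control fibroblasts with a control hairpin, microRNA cells that expressed miR-9/9* and miR-124 with the control hairpin, and REST-hairpin cells that expressed the microRNAs with a hairpin against REST. Both microRNA groups were at day 7 of conversion toward neurons. The libraries held 15674376 and 15782133 counts in control fibroblasts, 14223429 and 14587073 in microRNA cells, and 12754671 and 13923514 in REST-hairpin cells. FN1, which encodes the matrix protein fibronectin, took 7.41% and 7.17% of counts in control fibroblasts, 1.39% and 1.41% in microRNA cells, and 2.83% and 2.62% in REST-hairpin cells. Protein-coding genes took 95.4% to 96.4% of counts and mitochondrially encoded genes 3.29% to 4.64%. Levels are TMM-scaled CPM, counts relative to library size, as mean ± SD of 2 libraries.

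REST, the target of the hairpin (ENSG00000084093, chromosome 4, 57774075 to 57802010 on hg19), was measured at 101 and 104 CPM in the control fibroblast libraries, 143 and 146 CPM in the microRNA libraries, and 11.3 and 12.4 CPM in the REST-hairpin libraries. Against control fibroblasts it rose with the microRNAs by a log2 fold change of 0.50 (SE 0.05, n = 2 per group, edgeR adjusted p = 1.52e-16). With the hairpin it fell by 3.61 on the log2 scale against microRNA cells (SE 0.07, adjusted p = 8.52e-72), which is 12.2-fold, and fell by 3.11 against control fibroblasts (SE 0.07, adjusted p = 8.35e-64).

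The first comparison asks what the microRNAs did to fibroblasts that carried the control hairpin. The sources used here give neither the day of the control fibroblasts nor the contents of the microRNA vector. Differences of day or of other vector contents therefore cannot be told apart from effects of the microRNAs. Changes described below as occurring with the microRNAs carry that limit. COL1A1, the main chain of type I collagen, went from 17659 ± 187 to 2185 ± 80.3 CPM (n = 2 per group), and ITGB1, the beta subunit of many integrins, from 1797 ± 19.1 to 89.2 ± 4.93 CPM. Several neuronal genes were higher: MAP2, a dendritic microtubule protein, went from 3.14 ± 0.392 to 43.3 ± 1.90 CPM and SCG2, a secretory granule protein, from 1.09 ± 0.113 to 43.6 ± 2.15 CPM. PTBP1, a splicing repressor that gives way to PTBP2 in neurons, fell from 212 ± 4.76 to 60.7 ± 1.42 CPM while PTBP2 rose from 20.5 ± 2.52 to 103 ± 5.19 CPM.

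Of 17216 genes tested with edgeR, 6065 rose and 5826 fell at an adjusted p under 0.05, of which 2375 and 2395 changed over 2-fold and 862 and 659 over 4-fold. Libraries of the compared groups did not overlap in 83.4% of genes, against 33.3% by chance. The largest rise was at MIR124-2, a microRNA gene (chromosome 8, 65291706 to 65291814 on hg19), with 459 ± 5.56 CPM, at least 3941-fold above 0 counts. Next was ENSG00000207819 (chromosome 15, 89911248 to 89911337), with 262 ± 17.8 CPM, at least 2249-fold higher. It is given by its identifier because the symbol table used here held no name for it. The counts do not tell transcripts of these loci from those of the microRNA vector, whose contents are not given in the sources used here. SPARCL1, a matricellular protein gene, reached 58.0 ± 0.640 CPM from 0 counts, at least 499-fold higher. MIR3659HG and NAP1L2 were at least 48.0-fold and 40.6-fold higher, and ABCA12 was 372-fold above 2 counts (95% counting interval 103 to 3079). The largest falls were LEP (leptin), 255-fold lower with 2 counts left (interval 70.3 to 2116), LINC00968 (log2 fold change -6.55, SE 0.19), ADH1B (-6.48, SE 0.19), EGFL6 (73.7-fold with 3 counts left, interval 24.8 to 361), CCN5 (-5.97, SE 0.07) and TNFRSF11B (-5.89, SE 0.06). In all 115 named results of this comparison that passed the test, the libraries of the groups did not overlap. In every comparison the naming rule favours such genes. It requires separate libraries for the largest changes and takes list members by the smallest adjusted p.

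Among reported targets of miR-9/9* and miR-124, 36 of 44 measured members fell and 5 rose (median log2 fold change -1.35, camera adjusted p = 7.88e-25), and the call held with an estimated correlation (adjusted p = 0.0134). ITGB1 fell by 4.33 on the log2 scale (SE 0.05), RDH10 fell by 4.18 (SE 0.08), VAMP3 fell by 3.47 (SE 0.07) and IQGAP1 fell by 2.60 (SE 0.05). REST itself and 4 other members were higher. In the fibroblast matrix and identity list 39 of 46 members fell and 5 rose, and adjusted over the list alone 39 fell and 6 rose (median -1.16, adjusted p = 1.18e-28). That call also held with an estimated correlation (adjusted p = 0.0134). CCN2, a growth factor of connective tissue, fell by 4.15 (SE 0.05), FBN1, a microfibril protein, fell by 3.73 (SE 0.05), and LOX, which crosslinks collagen, fell by 3.55 (SE 0.05). For every other list of this comparison, the counts adjusted over the list alone were those over all genes.

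Canonical REST target genes rose in 26 of 40 measured members and fell in 3 (adjusted p = 0.00464; adjusted p = 0.186 with an estimated correlation), although REST RNA was higher. NEFM, a neurofilament chain, rose by 5.61 (SE 0.22) and the sodium channel SCN2A by 4.57 (SE 0.19), whereas STMN2, a tubulin-binding growth cone protein, fell from 169 ± 6.21 to 70.9 ± 4.89 CPM. The list's median log2 fold change was 1.49, or 0.92 with the 4 members at 0 counts in a group set to their bound. Presynaptic and vesicle release genes rose in 18 of 29 members and fell in 4 (median 1.30, or 0.93 with bounds; adjusted p = 0.0189; adjusted p = 0.210 with an estimated correlation). SYT11 rose by 1.60 (SE 0.05) and DNM3 by 2.51 (SE 0.10), RAB3B fell by 0.82 (SE 0.04), and SNAP25, a fusion protein of synaptic vesicles, rose from 0.155 ± 0.000411 to 0.992 ± 0.247 CPM. Of 6 measured neuronal BAF and splicing factors 5 rose (adjusted p = 0.0201; adjusted p = 0.294 with an estimated correlation), among them DPF1 by 2.24 (SE 0.22) and NOVA1 by 1.52 (SE 0.15). ACTL6B had 1 count in each group, too few for a fold, and ACTL6A was at 27.3 ± 0.127 and 26.2 ± 1.97 CPM (adjusted p = 0.507; higher by 0.39 with library totals).

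Other lists that passed the test were p53 targets and growth arrest (20 of 25 rose, 3 fell; adjusted p = 3.78e-09; adjusted p = 0.117 with an estimated correlation), interferon-stimulated genes (18 of 28 rose, 6 fell; adjusted p = 0.0230; adjusted p = 0.210 with an estimated correlation), smooth muscle and contractile genes (13 of 16 fell, 1 rose; adjusted p = 2.11e-08; adjusted p = 0.243 with an estimated correlation) and unfolded protein and amino acid stress genes (19 of 22 fell, 1 rose; adjusted p = 9.62e-13; adjusted p = 0.129 with an estimated correlation). GADD45A, a growth arrest gene, rose by 2.07 (SE 0.05) and FDXR by 2.21 (SE 0.06). IFI6 rose by 3.57 (SE 0.06), whereas STAT2, a transcription factor of the interferon response, fell by 0.90 (SE 0.04). TAGLN fell by 2.67 (SE 0.06) and CALD1 fell by 1.75 (SE 0.05). TRIB3 fell by 3.93 (SE 0.09) and PHGDH, the entry enzyme of serine synthesis, fell by 3.15 (SE 0.07).

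REST corepressor and PRC2 components rose in 13 of 23 members and fell in 8 without passing the list test (adjusted p = 0.570). With library totals 19 of them rose and 4 fell. The small phosphatases CTDSP1, CTDSP2 and CTDSPL, which act with REST, had log2 fold changes of -2.96 (SE 0.06), -2.51 (SE 0.05) and -2.09 (SE 0.08), all past the test. RCOR1, the scaffold of the CoREST complex, fell by 0.82 (SE 0.08), USP14 fell by 0.64 (SE 0.08), SMARCA4 rose by 1.25 (SE 0.05) and EZH2, the PRC2 methyltransferase, rose by 0.78 (SE 0.15). TUBB3 rose by 0.58 (SE 0.18), a call that ended without control fibroblast replicate 2 (0.36, adjusted p = 0.138). Lists that did not pass were neurotransmitter receptors and postsynaptic proteins (17 rose and 3 fell of 26), neuronal cytoskeleton and adhesion (11 and 6 of 19), voltage-gated channels (14 and 10 of 28), cell cycle and DNA replication (8 and 27 of 39), cholesterol synthesis (14 and 3 of 21), cytokines (10 and 5 of 19) and immediate early genes (7 and 6 of 15). Neither did neurogenic transcription factors (6 and 5 of 14), progenitor BAF and splicing factors (1 and 3 of 5), skeletal muscle markers (1 and 1 of 3) or mitochondrially encoded transcripts (0 and 4 of 13) pass. With library totals the medians of these 4 lists went from -0.11, -0.33, -0.14 and -0.14 to 0.34, 0.12, 0.31 and 0.31. Median, mean and test differed in sign for neurogenic transcription factors and skeletal muscle markers (negative median, positive mean, test upward), for cytokines and astrocyte markers (positive median and mean, test downward), and for immediate early genes (positive median, negative mean, test downward).

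Markers of other cell types differed between lists, and none of these lists passed the test. Endothelial and blood cell markers rose in 8 of 10 members and fell in 2 (camera adjusted p = 0.350), with PTPRC at 4.34 ± 0.453 against 0.271 ± 0.164 CPM. Their median log2 fold change was 2.41, or 2.37 with the member at 0 counts in a group set to its bound. Astrocyte and glial markers rose in 5 and fell in 2 of 10, neural progenitor markers rose in 3 and fell in 1 of 6 (CDH2 by 1.80, SE 0.06), and epithelial and melanocyte markers rose in 1 and fell in 3 of 8. DNMT3B, the single pluripotency marker measured, was at 3.30 ± 0.595 and 2.45 ± 0.178 CPM, which did not pass the test (log2 fold change -0.42, SE 0.24), and the sign of its change turned with library totals. Scaling by library totals in place of TMM moved the median of all genes by 0.45 and the share of higher calls from 51.0% to 74.6%, with 9783 higher and 3326 lower. Under it the list calls of REST targets (adjusted p = 0.0864) and presynaptic genes (adjusted p = 0.0849) ended, although their medians were 1.93 and 1.75, higher by about the shift of all genes. Calls were gained there for cell cycle genes (downward, adjusted p = 0.0414), cholesterol synthesis (upward, adjusted p = 0.0414) and neural progenitor markers (upward, adjusted p = 0.0449), so 10 lists passed against 9.

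**Figure D1:**
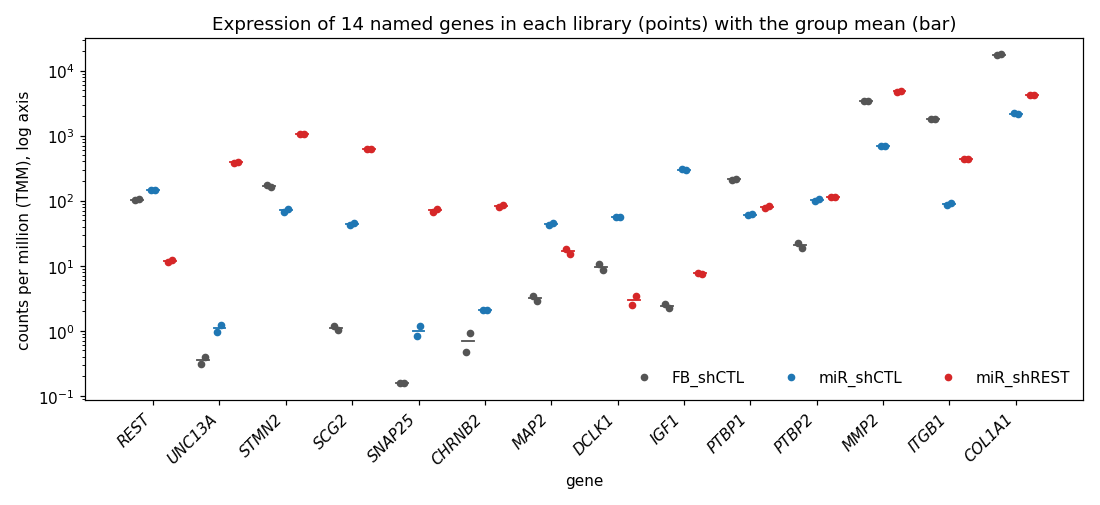
Levels of 14 named genes in TMM-scaled CPM on a log axis; each point is a library and each bar the mean of 2 libraries, for control fibroblasts (FB_shCTL), microRNA cells (miR_shCTL) and REST-hairpin cells (miR_shREST). REST lies at 11.8 CPM in REST-hairpin cells against 145 CPM in microRNA cells, while UNC13A lies at 386 CPM against 1.09 CPM.

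The second comparison, the main question of the series, asks what the REST hairpin added in cells that expressed the microRNAs. UNC13A, which primes synaptic vesicles for release (chromosome 19, 17712137 to 17799401 on hg19), went from 1.09 ± 0.201 CPM in microRNA cells to 386 ± 5.69 CPM in REST-hairpin cells, a log2 fold change of 8.46 (SE 0.09, n = 2 per group, adjusted p = 1.61e-95). SNAP25 went from 0.992 ± 0.247 to 70.7 ± 3.82 CPM, STMN2 from 70.9 ± 4.89 to 1055 ± 16.3 CPM, SCG2 from 43.6 ± 2.15 to 624 ± 0.910 CPM and CHRNB2, a nicotinic receptor subunit, from 2.08 ± 0.00838 to 82.7 ± 3.19 CPM. Other neuronal genes were lower: MAP2 went from 43.3 ± 1.90 to 16.55 ± 1.84 CPM and DCLK1, a neuronal microtubule kinase, from 56.1 ± 0.300 to 2.95 ± 0.701 CPM. IGF1, a growth factor, went from 297 ± 8.58 to 7.65 ± 0.220 CPM, and MMP2, a matrix protease, from 687 ± 9.09 to 4786 ± 46.8 CPM.

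With edgeR, 5185 genes rose and 5273 fell, of which 1321 and 1351 changed over 2-fold and 242 and 284 over 4-fold. Libraries did not overlap in 78.5% of genes, against 33.3% by chance, nor in any of the 107 named results that passed the test. With UNC13A, the largest rises included SCG3 by 8.67 (SE 0.17) and CHGB by 8.24 (SE 0.16), both secretory granule proteins. SCG3 and CHGB had 6 and 9 counts over the microRNA libraries, so counting error alone is larger than these SEs. ACTL6B, the BAF subunit of neurons, had 1 count in microRNA cells and 389 in REST-hairpin cells, 433-fold higher (95% counting interval 77.3 to 17145). GOLGA7B was at least 96.8-fold above 0 counts, and GPR19, an orphan receptor, was 176-fold above 2 counts (interval 48.3 to 1458). The largest falls were SPARCL1 (log2 fold change -6.24, SE 0.15), IGF1 (-5.28, SE 0.07), TMEM100 (-4.62, SE 0.20), TSPAN18 (-4.32, SE 0.08), DCLK1 (-4.24, SE 0.12) and SUSD4 (-4.16, SE 0.28).

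Canonical REST target genes rose in 29 of 40 measured members and fell in 8, and adjusted over the list alone 31 rose and 8 fell. The median log2 fold change was 2.41 (camera adjusted p = 6.42e-45), and the call held with an estimated correlation (adjusted p = 0.0116). The whole list has 61 members, and the filter left out those with few counts in every group. Without the filter 32 members rose and 8 fell. CELSR3, an adhesion receptor of developing axons, rose by 4.53 (SE 0.07), STMN2 by 3.89 (SE 0.05) and SCG2 by 3.84 (SE 0.05), whereas SCN2A fell by 2.45 (SE 0.13). Presynaptic and vesicle release genes rose in 13 of 29 members and fell in 10 (median 0.68, adjusted p = 0.00127; adjusted p = 0.154 with an estimated correlation). SYN1, a synaptic vesicle phosphoprotein, rose by 5.79 (SE 0.21) and BSN, an active zone scaffold, by 4.06 (SE 0.10). Of these 29 genes, 9 are also in the REST target list, where 6 rose and 3 fell, and of the other 20 members 7 rose and 7 fell. The presynaptic call ended when any library of the data set was left out, with adjusted p from 0.161 to 0.239.

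Reported targets of miR-9/9* and miR-124 rose in 29 of 44 members and fell in 5 (median 0.40, adjusted p = 6.12e-06; adjusted p = 0.101 with an estimated correlation). ITGB1 rose by 2.29 (SE 0.05) and IQGAP1, a cytoskeletal scaffold, by 1.81 (SE 0.05) and LAMC1, a laminin chain, rose from 620 ± 10.2 to 1753 ± 18.7 CPM. Fibroblast matrix and identity genes rose in 27 of 46 members and fell in 14 (median 0.37, adjusted p = 4.76e-05; adjusted p = 0.101 with an estimated correlation). MMP2 rose by 2.80 (SE 0.05), NT5E by 2.47 (SE 0.05), LOX by 2.24 (SE 0.05) and COL1A1 by 0.94 (SE 0.05), whereas COL6A3, a chain of type VI collagen, fell by 1.90 (SE 0.05). The counts of these 2 lists were the same adjusted over the list alone. REST corepressor and PRC2 components fell in 12 of 23 members and rose in 7 (median -0.14, adjusted p = 0.0483; adjusted p = 0.761 with an estimated correlation). REST is a member of that list and of the microRNA target list. RBBP4, a histone-binding subunit of several repressor complexes, fell by 1.41 (SE 0.07), HMG20B fell by 1.13 (SE 0.08) and SIN3B fell by 0.80 (SE 0.05). That list call ended when any library was left out, with adjusted p from 0.131 to 0.239.

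PTBP1 rose by 0.39 (SE 0.06) and ACTL6A by 0.66 (SE 0.07), RCOR1 rose by 0.39 (SE 0.09) and TUBB3 fell by 0.54 (SE 0.17). PTBP2 rose by 0.16 (SE 0.05), a call that ended without microRNA replicate 1 (0.09, adjusted p = 0.210), and USP14 was at 27.9 ± 1.66 and 30.4 ± 2.48 CPM (adjusted p = 0.184). EZH2 rose by 0.29 (SE 0.13, adjusted p = 0.0435), a call that ended when any of the 6 libraries was left out, with values from 0.23 to 0.33. No other list passed the test. Neuronal cytoskeleton and adhesion genes rose in 5 and fell in 9 of 19 members, with INA, an axonal filament protein, higher by 2.06 (SE 0.06) and TUBA1A lower (-1.45, SE 0.06). Voltage-gated channels rose in 7 and fell in 15 of 28, and adjusted over the list alone 8 rose. The sodium channel SCN8A rose by 1.01 (SE 0.07). Neurotransmitter receptors and postsynaptic proteins rose in 8 and fell in 9 of 26, with GLRB, a glycine receptor subunit, higher by 1.39 (SE 0.07) and DLG4, the scaffold PSD-95, lower (-1.06, SE 0.07). Neurogenic transcription factors rose in 4 and fell in 6 of 14, with SOX4 lower (-1.39, SE 0.05) and MEF2C lower (-0.84, SE 0.06).

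Interferon-stimulated genes rose in 18 and fell in 5 of 28 (adjusted p = 0.596), and 6 fell adjusted over the list alone. IFI6 was among those that fell, with a log2 fold change of -0.85 (SE 0.05). Among p53 targets 14 rose and 7 fell of 25, or 15 and 7 adjusted over the list alone, with CDKN1A, the cell cycle inhibitor p21, higher by 0.73 (SE 0.04). Unfolded protein and amino acid stress genes rose in 6 and fell in 9 of 22, or 7 and 9 over the list alone, and the chaperone HSPA5 fell by 1.02 (SE 0.05). Counts of genes that rose and fell were 15 and 5 of 39 for cell cycle and DNA replication, 5 and 9 of 16 for smooth muscle, 7 and 8 of 21 for cholesterol synthesis, 7 and 6 of 19 for cytokines, 9 and 3 of 15 for immediate early genes, 2 and 2 of 5 for progenitor BAF factors, and 3 and 2 of 6 for neuronal BAF factors. Among cytokines, CXCL12 fell by 1.78 (SE 0.05) and IL1A rose by 3.22 (SE 0.17). Mitochondrially encoded transcripts rose in 6 of 13, or 4 adjusted over the list alone, and 0 fell. Of the markers of other cell types, 3 rose and 3 fell of 10 astrocyte and glial markers, 0 and 5 of 10 endothelial and blood cell markers (4 fell over the list alone), 0 and 3 of 6 neural progenitor markers (4 fell over the list alone), 3 and 2 of 8 epithelial and melanocyte markers, and 0 and 0 of 3 skeletal muscle markers. DNMT3B was at 2.45 ± 0.178 and 2.87 ± 0.126 CPM (adjusted p = 0.421).

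Median, mean and list test differed in sign for neuronal cytoskeleton (median -0.17, mean -0.10, test upward), receptors (median -0.0024, mean 0.37, test upward), neurogenic transcription factors (median -0.23, mean 0.03, test downward) and cytokines (median 0.31, mean 0.04, test downward). The median of neuronal BAF factors was 0.04, or -0.000603 with library totals, which moved the median of all genes by -0.04 and under which the smooth muscle list passed, downward (adjusted p = 0.0491). The DESeq2 test called 3416 genes higher where edgeR called 5185.

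**Figure D2:**
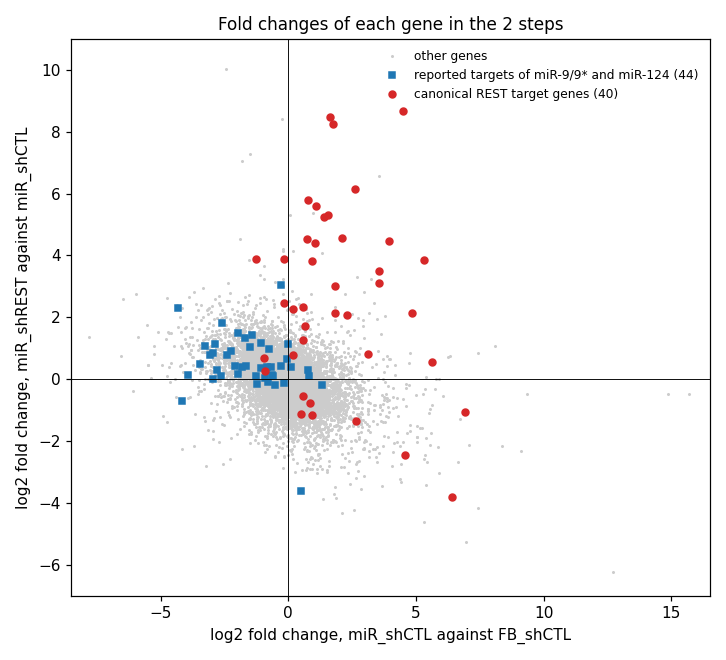
Log2 fold change of each gene between REST-hairpin and microRNA cells (vertical) against that between microRNA cells and control fibroblasts (horizontal), with 40 REST target genes as circles and 44 reported microRNA targets as squares; values of genes with 0 counts in a group are fitted values. The REST targets have medians of 1.49 and 2.41 on the horizontal and vertical axes, and the microRNA targets -1.35 and 0.40, and these signs were the same with library totals.

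The third comparison sets REST-hairpin cells against control fibroblasts. It covers the microRNAs and the REST hairpin together, with any difference of day or vector contents. SCG2 stood at 624 ± 0.910 CPM against 1.09 ± 0.113 CPM (n = 2 per group), UNC13A at 386 ± 5.69 against 0.349 ± 0.0539 CPM, and SNAP25 at 70.7 ± 3.82 against 0.155 ± 0.000411 CPM. COL1A1 fell by 2.07 on the log2 scale (SE 0.05), from 17659 ± 187 to 4201 ± 4.12 CPM, and MAP2 rose by 2.39 (SE 0.15). PTBP1 fell by 1.41 (SE 0.05), PTBP2 rose by 2.48 (SE 0.07), ACTL6A rose by 0.60 (SE 0.08) and EZH2 rose by 1.07 (SE 0.15), while TUBB3 was at 4.56 ± 0.212 and 4.42 ± 0.999 CPM (adjusted p = 0.852). RCOR1 fell by 0.43 (SE 0.08) and USP14 fell by 0.52 (SE 0.08), calls that ended with library totals (-0.03 and -0.11).

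With edgeR, 5792 genes rose and 5765 fell, of which 2236 and 2192 changed over 2-fold and 852 and 628 over 4-fold. Libraries did not overlap in 82.1% of genes, against 33.3% by chance. Of 110 named results past the test, 109 had separate libraries, the exception being MT-CYB. SCG3 was at least 682-fold above 0 counts, SVOP, a synaptic vesicle protein, at least 82.6-fold, and MIR124-2 and ENSG00000207819 at least 2840-fold and 1624-fold. ACTL6B was 347-fold above 1 count (95% counting interval 61.9 to 13728) and CHGB 1121-fold above 2 counts (interval 310 to 9263). The largest falls were EGFL6 (99.3-fold with 2 counts left, interval 27.1 to 826), LEP (log2 fold change -6.45, SE 0.29), OMD (93.1-fold with 3 counts left, interval 31.5 to 455), HAPLN1 (-6.13, SE 0.31), the feature ENSG00000124693, given by its identifier (-6.11, SE 0.31), and UBL4B (70.7-fold with 3 counts left, interval 23.8 to 346).

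Canonical REST target genes rose in 34 of 40 members and fell in 3 (median 4.54, or 3.97 with 4 members at their bound; adjusted p = 1.93e-23), and the call held with an estimated correlation (adjusted p = 0.0319). Members called lower numbered 0 with library totals, 0 against a fold of 1.5 and 1 with the DESeq2 test. CELSR3 rose by 5.24 (SE 0.08) and STMN2 by 2.64 (SE 0.05). Calls also held with an estimated correlation for reported microRNA targets (7 rose and 33 fell of 44; adjusted p = 2.88e-12 and 0.0332) and fibroblast matrix and identity genes (8 rose and 35 fell of 46; adjusted p = 8.23e-15 and 0.0319). RDH10 fell by 4.90 (SE 0.09), CTDSP1 fell by 2.94 (SE 0.06) and CCN2 fell by 3.15 (SE 0.05). Presynaptic genes rose in 19 of 29 and fell in 5 (adjusted p = 1.87e-05; adjusted p = 0.0708 with an estimated correlation), with BSN higher by 5.37 (SE 0.13). Neuronal BAF and splicing factors rose in 5 of 6 (adjusted p = 0.00122; adjusted p = 0.209 with an estimated correlation). p53 targets rose in 21 of 25 and fell in 1 (adjusted p = 4.63e-12; adjusted p = 0.0504 with an estimated correlation), with GADD45A higher by 2.52 (SE 0.05). Interferon-stimulated genes rose in 19 of 28 and fell in 5 (adjusted p = 4.46e-04; adjusted p = 0.0834 with an estimated correlation), with IFI6 higher by 2.73 (SE 0.06) and STAT2 lower (-1.89, SE 0.05). Smooth muscle genes fell in 13 of 16 and rose in 2 (adjusted p = 1.61e-10; adjusted p = 0.186 with an estimated correlation), with TAGLN lower (-3.89, SE 0.07). Unfolded protein and amino acid stress genes fell in 19 of 22 and rose in 1 (adjusted p = 4.64e-15; adjusted p = 0.0769 with an estimated correlation), with TRIB3 lower (-3.81, SE 0.09).

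No other list passed. Members that rose and fell were 17 and 5 of 26 for receptors and postsynaptic proteins, 11 and 6 of 19 for neuronal cytoskeleton, 12 and 10 of 28 for channels (13 rose over the list alone), 7 and 6 of 14 for neurogenic transcription factors, 1 and 4 of 5 for progenitor BAF factors, 8 and 23 of 39 for cell cycle, 14 and 4 of 21 for cholesterol synthesis, 9 and 7 of 19 for cytokines (10 rose over the list alone), 8 and 6 of 15 for immediate early genes, and 1 and 0 of 3 for skeletal muscle. With library totals, cell cycle genes rose in 13 and fell in 15, and progenitor BAF factors rose in 2 and fell in 1. KRT19 fell by 2.68 (SE 0.11) and CDH2 rose by 1.82 (SE 0.06). For mitochondrially encoded transcripts 4 rose and 3 fell of 13 (3 and 3 over the list alone), and for endothelial and blood cell markers 5 and 2 of 10. The medians of 4 further lists were negative and turned positive with library totals: REST corepressor and PRC2 components (8 rose and 11 fell of 23, or 9 and 13 adjusted over the list alone), astrocyte (3 and 2 of 10), neural progenitor (2 and 2 of 6) and epithelial and melanocyte markers (2 and 4 of 8). DNMT3B was at 3.30 ± 0.595 and 2.87 ± 0.126 CPM (adjusted p = 0.455), and its sign turned too. Median and list test differed in sign for astrocyte (-0.0039, test upward) and neural progenitor markers (-0.18, test upward). Library totals moved the median of all genes by 0.40 and the share of higher calls from 50.1% to 74.0%, with 9397 higher and 3311 lower.

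**Figure D3:**
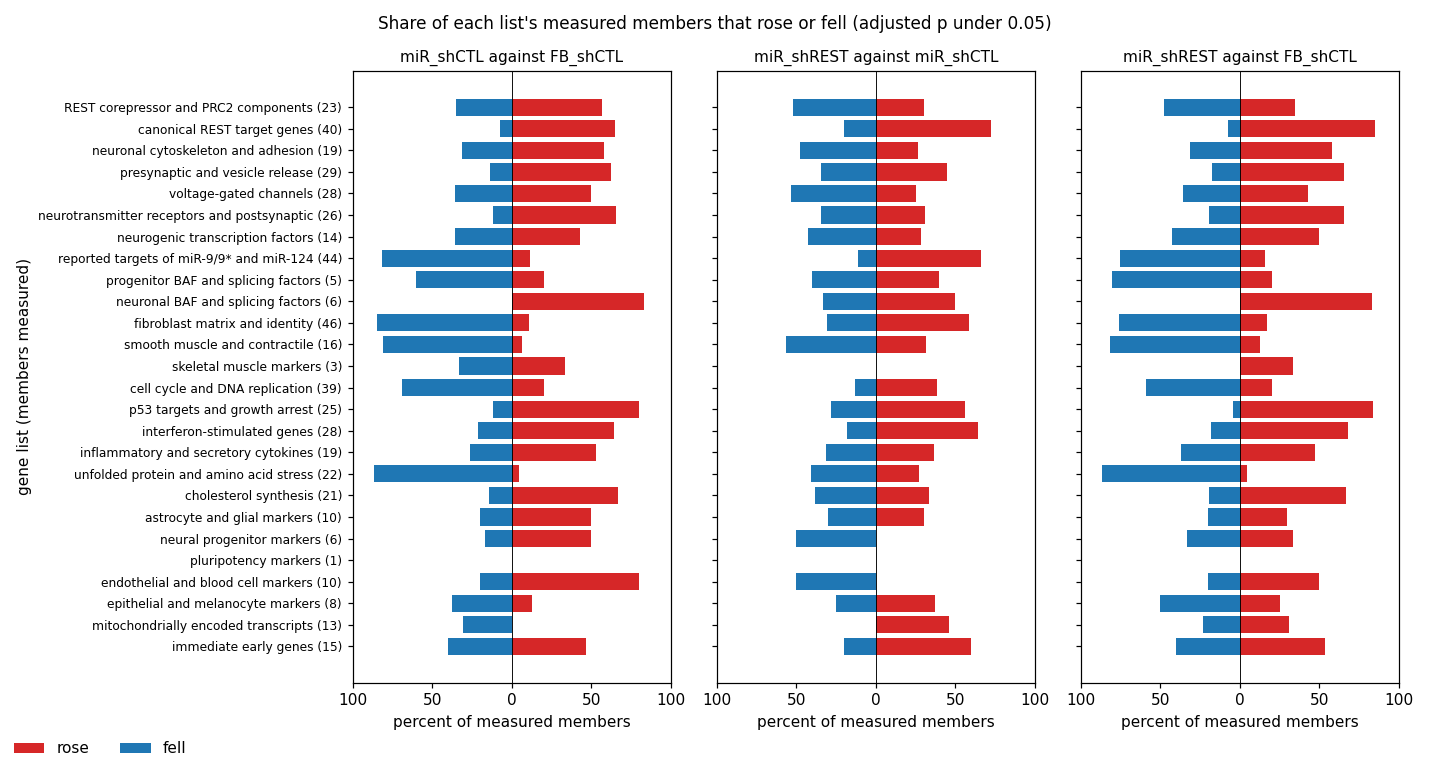
Percent of the measured members of each of 26 gene lists that rose (right) or fell (left) at an edgeR adjusted p under 0.05, for each comparison, with the number of measured members in brackets. REST target genes rose in 26, 29 and 34 of 40 members; with library totals the medians of 5 lists change sign in the first comparison and 5 in the third (neurogenic factors, progenitor BAF, skeletal muscle and mitochondrial genes in the first, REST corepressor, astrocyte, neural progenitor and epithelial genes in the third, pluripotency in both), and that of neuronal BAF factors in the second.

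The 2 steps were set side by side, since the microRNA cells end the first and begin the second. Of the genes that rose with the microRNAs 3082 fell with the REST hairpin (50.8%), where independent lists would share 1858, and 1002 rose again, where independent lists would share 1827. Of the genes that fell with the microRNAs 2862 rose with the REST hairpin (49.1%, against 1755 for independent lists) and 1182 fell again (against 1784). ITGB1 and COL1A1 were among those that fell and then rose, MAP2 and IGF1 among those that rose and then fell, and SCG2 and SNAP25 rose in both steps. In 20 simulations with no effect at most 2 genes overlapped in any direction. Those data sets held no changed genes, so this count cannot show how many opposite calls shared libraries add when many genes change. The covariance of the log2 fold changes across 13416 genes was -0.320, against a simulated mean of -0.00821 (range -0.00876 to -0.00795), and the correlation across genes, which are not independent replicates, was -0.37, against a simulated -0.50. The microRNA group has too few libraries to leave 2 for each comparison when split, so part of the excess may come from the shared libraries. The simulations drew only the spread between libraries of a group, so they cannot show the effect of a deviation common to both microRNA libraries.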

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

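The tests on shared libraries, on unconverted fibroblasts and on seed sites with the microRNA response as a term were chosen after their results were seen. In 1096 genes the microRNA cells and the REST-hairpin cells lay on opposite sides of control fibroblasts, each past the edgeR test, and the difference between the microRNA groups passed its own test too. Of these, 462 were below control fibroblasts in microRNA cells and above them in REST-hairpin cells, 634 were the reverse, and 46 were over 2-fold away both ways. Among the named genes reported here 14 did so. Below and then above fibroblasts, the difference of REST-hairpin from microRNA cells was 3.89 for STMN2, 2.80 for MMP2, 2.47 for NT5E, 1.06 for VCL, 1.01 for SCN8A, 0.73 for CDKN1A, 0.69 for TNFRSF10B and 0.52 for MT-CO3 on the log2 scale. Above and then below fibroblasts, it was -4.32 for TSPAN18, -4.24 for DCLK1, -3.61 for REST, the target of the hairpin, -1.41 for RBBP4, -1.06 for DLG4 and -0.27 for DPF2. With library totals MT-CO3 was above fibroblasts in both groups (0.13 in microRNA cells), and the DPF2 rise in microRNA cells ended under several alternatives. In the p53 list, which holds CDKN1A and TNFRSF10B, members called lower with the microRNAs went from 3 to 1 with library totals. At least 1 of these genes therefore lost that call. The counts of 1096, 462 and 634 genes rest on TMM scaling and were not repeated with library totals, which shift the median of all genes.

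Among genes moved by the microRNAs, opposite moves with the REST hairpin outnumbered moves in the same direction. Of those that rose, 3082 fell and 1002 rose again, and of those that fell, 2862 rose and 1182 fell again. Spread between libraries of a group, shared through the microRNA libraries, is argued against as the whole cause. The covariance of -0.320 lies outside the -0.00876 to -0.00795 simulated from that spread. A deviation common to both microRNA libraries was not in the simulations. It would also give a negative covariance, so it stays open. A single share of cells with the profile of control fibroblasts is also argued against as the whole cause. Of 79 abundant genes that the microRNAs lowered over 8-fold, 56 lay over 3 SE from the fold of the median share of 6.01%. That is 70.9% (95% exact interval 59.6% to 80.6%), and 8 of the 79 fell further, among them MFAP4 by 1.36. A first version of that test, the 10.1% that fell further, did not decide. Unconverted cells in these cultures would carry the REST hairpin, and no fibroblasts with that hairpin alone were sequenced. Their profile is unknown, so a share of unconverted cells stays open as part of the pattern. Lower microRNA activity in REST-hairpin cells may contribute, since genes with the miR-124 seed site rose (effect 0.17, SE 0.02, t 8.24). By t, this site ranked 1 from the highest of 15892 7-mers, or 0.00629% from the top. With each gene's own microRNA response as a term, the effect was 0.07 and the rank 29, without that term miR-9* sites ranked 73 and miR-9 sites 4209, MIR124-2 was at 330.5 CPM against 459 CPM in microRNA cells, and an effect of lowering REST itself also stays open.

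REST target genes rose with the microRNAs although REST RNA rose too. Reads carried over from the REST-hairpin libraries are argued against, since 23 of 26 members (88.46%) stayed higher after the largest carry-over the libraries allow, 0.242%, was taken off. A general rise of genes with low expression is argued against by the list's median of 1.49, which was at percentile 100 of 10000 random lists matched on expression (central range -0.17 to 0.57). The call ended with an estimated correlation (adjusted p = 0.186) and with library totals, where the medians of the list and of all genes rose alike, from 1.49 and 0.04 to 1.93 and 0.49. No biological explanation of this rise was tested.

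Neuronal genes outside the REST target list fell more often than they rose with the REST hairpin (42 fell and 24 rose of 94; median -0.24). The general return of genes raised by the microRNAs could account for it, since the median left after each gene's own microRNA response was -0.0588, within the -0.135 to 0.135 of random lists. Matches to a hairpin seed cannot be told apart from this, since members without the 6-mer had a median of -0.20 (95% bootstrap interval -0.70 to 0.10). The 30 members with the 6-mer had a median of -0.61 (18 fell, 6 rose), and the 29 not searched a median of 0.52 (6 fell, 8 rose). That interval reaches 0, which the prediction written beforehand would have counted for the seed, but 18 of these 35 members fell and 10 rose, so a weaker verdict was kept.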

How the results depend on the processing

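The removal of carry-over was chosen after the data were seen (6052 genes higher with the microRNAs), and all other alternatives were fixed before the data were examined. Of 4497 values of named genes under 13 alternatives, 4382 kept direction and side of the threshold, 91 lost the call, 6 gained it, 7 reversed and 11 changed sign uncalled in both. Most named genes were picked by size of change or adjusted p, so these counts do not describe all genes. Most losses came from the test against a fold of 1.5 (48) and the DESeq2 test (13).

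With library totals, which shift the median of all genes, the first comparison had 9783 higher and 3326 lower and the third 9397 and 3311; overlaps became 1784 (higher in both steps), 1796 (lower then higher) and 568 (lower in both). In the first comparison ACTL6A reversed to 0.39, SS18 to 0.12, MT-CYB to 0.0131, MT-CO3 to 0.13 and MT-CO2 to 0.20, and in the third EMX2 to 0.0931 and MT-CYB to 0.23. Against a fold of 1.5, a stricter test by construction, higher and lower counts were 2828 and 3040, 1595 and 1758, and 2598 and 2811, and the overlaps 123, 822, 795 and 162 (higher-higher, higher-lower, lower-higher, lower-lower). The DESeq2 test called 3416 higher in the second comparison, with overlaps of 472, 2040 and 775 (higher-higher, higher-lower, lower-lower) and without the TUBB3 call in the first and second comparisons; the cause was not tested. Lists past the threshold were 9, 5 and 9, with an estimated correlation 2, 1 and 3, and with fry, which tests another question, 20, 20 and 21.

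Leaving out each library in turn, where the lone sample is assumed to vary like the other groups, left 3 to 4 lists in the second comparison, the presynaptic and REST corepressor calls ending each time. It gave 4442 to 5128 genes higher in that comparison. EZH2 lost its call in the second comparison when any of the 6 libraries was left out, PAX6 without microRNA replicate 1 or either REST-hairpin library, and NOVA1 without REST-hairpin replicate 1, each keeping its direction. The mitochondrial list passed without control fibroblast replicate 1 (adjusted p = 0.00443), replicate 2 (0.00490) or REST-hairpin replicate 1 (0.0310). With a replicate block the counts were 6041 and 5796, 5157 and 5259, and 5767 and 5756, and no named gene changed its call; same-numbered libraries did not deviate together (correlations -0.06, 0.08 and -0.0028 over 10172 genes), so the numbers do not pair the samples. Depth limits genes with few counts, such as ACTL6B with 1 count in control fibroblasts.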

Other observations

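The tests on GTGTATC by site type and with the microRNA response as a term were chosen after the results were seen, as was BCL2L1. BCL2L1, which encodes the survival protein Bcl-xL (chromosome 20, 30252255 to 30311792 on hg19), was at 99.2 ± 2.37 CPM in control fibroblasts, 5338 ± 83.3 CPM in microRNA cells and 4295 ± 85.5 CPM in REST-hairpin cells (n = 2 each). It rose by 5.75 with the microRNAs (SE 0.06, edgeR adjusted p = 2.88e-99) and fell by 0.31 with the REST hairpin (SE 0.04). The contents of the microRNA vector are not given in the sources used here, and the counts do not tell transcripts of the chromosomal gene from those of a vector that carried it. Among all 15892 7-mers of 3' untranslated regions in 11321 genes, the miR-124 seed site GTGCCTT had the lowest rank with the microRNAs (1963 genes, effect -0.39, SE 0.03). The miR-9 site ACCAAAG ranked 10 from the lowest (-0.17, SE 0.03) and the miR-9* site AGCTTTA ranked 158 (-0.08, SE 0.03). Mature microRNAs were not measured.

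With the REST hairpin the 7-mer with the lowest rank of all was GTGTATC (891 genes; effect -0.39, SE 0.03, t -14.1), which had ranked 2192 with the microRNAs (-0.05, SE 0.04). Of 823 genes lower over 2-fold, 166 carried it (20.2%), against 7.87% of all genes. IGF1 carried its 8-mer form, DCLK1, SUSD4, MYL9 and COL6A3 a 7-mer form and TSPAN18 and SCN2A the form with A, whereas LAMC1 and FBN1 carry a 7-mer form and rose, and SPARCL1, the largest fall (-6.24), MAP2 and SOX4 have no site and fell. A hypothesis is that the hairpin may act on such sites as a small RNA does. Median fold changes followed site type, from -0.38 for the 8-mer (301 genes, 95% bootstrap interval -0.47 to -0.29) through -0.29, -0.15 and -0.08 for weaker sites to 0.04 with none. Of the genes with none, 342 had the 7-mer in coding or 5' untranslated sequence. Their median was -0.20 (interval -0.27 to -0.14), against 0.05 for the rest. That contrast had no terms for sequence length or base composition, so it cannot show whether sites outside the 3' region mattered. With the microRNAs alone, genes with the 8-mer were already lower (median -0.18, interval -0.25 to -0.05, against 0.04 with no site). With the microRNA response as a term, the effect of the 7-mer was -0.40 (t -15.7) and its rank still 1. The 8-mer had not been looked at beforehand, whereas the order of the 7-mer forms had. The 7-mer occurs in 10 of 12 annotated REST transcripts, at position 1061 of a coding transcript of 7300 bases, but 30.3% of 7-mers occur in the longest of them by chance. The reversed 7-mer CTATGTG had a t of 0.283, so the same bases in that order had no such effect. This is a weak test of base composition, which was already a term, because GTGTATC was picked as the lowest of all. The sequence of the hairpin is not given in the sources used here, so the hypothesis stays open.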
